A study of Caenorhabditis elegans with 2 samples.

How the data were processed

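The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq), which maps where a protein sits on DNA. It was run on whole Caenorhabditis elegans young adults of mixed sex, 58 h old, carrying an integrated transgene that expresses the zinc finger protein ZTF-3 fused to GFP; the precipitating antibody recognised GFP. The only group has 2 samples, labelled biological replicates 4 and 5 and given separate biosample records, and no second condition or untagged strain was analysed here.

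Each replicate has a deposited list of candidate regions, peaks together with background, that was derived from its own alignments and 1 control, per the file headers. A pooled list was derived in the same way from both replicates. The thresholded list was derived from the per-replicate and pooled lists by the irreproducible discovery rate (IDR), a measure of how well ranks match between replicates, per the file headers. The peak caller, the aligner and their versions are not given in the sources used here. Coordinates are on ce11, per the labels, and are given 1-based. The deposited signal value of a region is the peak caller's strength score against the control, and the deposited −log10 q is its significance on a log scale. Both belong to the authors. The deposited summit offset, in bp from the region start, gave the summit position. Signal was used to describe, rank or filter regions within a list. Between the replicate lists it entered only correlations and the IDR fit, because the lists are on different scales. The median signal was 22.6 in replicate 4, 9.86 in replicate 5 and 28.0 in the pooled list. Each of these 3 lists holds 30000 regions. The thresholded list holds 534, and these were checked to be the 534 pooled regions of highest signal. The lists carry no read counts, so sequencing depth is unknown, and the precision of a peak's signal cannot be given. Intervals on shares are exact binomial 95% intervals over peaks and cover counting error only; peaks are not replicates.

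Regions were placed on the WBcel235 assembly (the same sequence as ce11; all regions lay inside its chromosome lengths) with Ensembl annotation release 115. A peak counted as supported by a replicate when its summit lay inside a candidate region of that replicate's list, and as strongly supported when that region was among the replicate's 534 strongest. Both shares were set beside 1000 random placements of the peaks on the same chromosomes. Strength was compared with Spearman's rho and with Pearson's r of log10 signal across peaks, with 10000 permutations. A 2-component copula mixture IDR was fitted to regions paired between the replicate lists, a separate fit that does not use the authors' software. The promoter window ran from 1000 bp upstream to 200 bp downstream of a protein-coding transcription start site (TSS). Introns, exons and intergenic summits were defined by protein-coding genes alone, so an intergenic summit can lie in or beside a non-coding RNA gene. Thresholded peaks were compared with the other pooled candidate regions by Fisher's exact test, two-sided. Shares per chromosome were tested with exact binomial tests against the shares of pooled candidate regions. Non-coding RNA genes were counted within 500 bp of a summit. The 35 gene lists, tissue markers included, were tested by Fisher's exact test against protein-coding genes with any candidate summit in the promoter window. Canonical 6-mers in 101 bp windows at summits were tested one-sided against 5 control windows per peak, drawn from other candidate regions of like GC content (5 bins) and TSS distance; their odds ratios were computed with a small constant added to each cell. All families were adjusted by the Benjamini-Hochberg method at 0.05. Runs were perfect dinucleotide repeats of at least 20 bp, counted with a peak when a summit lay within 200 bp.

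Genes were named by a rule set before the data were examined, as were the tests and gene lists. The rule names the protein-coding gene with the TSS nearest each of the 25 strongest peaks and any non-coding RNA gene within 500 bp, up to 4 members of each list with the strongest promoter peaks, and ztf-3 and unc-119, both carried by the transgene. For 6-mers it names the 5 with the lowest p. Dinucleotide runs and SL2 RNA genes were chosen after the data were seen. So were 3 alternatives: chromosome shares without peaks at tRNA genes, 6-mers without peaks at GT/CA runs, and RNA genes at intergenic summits alone. The other alternatives, set before the data were examined, changed the overlap that counts as shared, the IDR threshold, the promoter window, the RNA gene distance, the background of each test and the k-mer length, took the 267 strongest peaks, or left out each replicate. Leaving out a replicate meant taking the 534 strongest regions of the other replicate's own list. A 6-mer test with 1 peak per 1 kb and without peaks near tRNA genes was also set before the data were examined.

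The statistics were tested on simulated data. With 12206 simulated pairs drawn from the fitted mixture, the IDR fit called 614 pairs, of which 3.26% were irreproducible, and only 27.4% of the reproducible pairs. It called 0 pairs between unrelated lists. In the k-mer test an implanted 6-mer came out in place 1 of 2080, and 0 6-mers were called without an implant. Both used windows of other candidate regions split at random. The matching on GC content and TSS distance was therefore not tested. Random hits gave a called gene list in 6.00% of 50 runs. Random peak sets gave a called chromosome in 2.50% of 200 runs. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.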

Results

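Binding of the zinc finger protein ZTF-3, tagged with GFP, was mapped by ChIP-seq in whole young adult worms in 2 biological replicates, labelled 4 and 5. The thresholded set held 534 peaks on the 6 nuclear chromosomes of ce11. They had a median width of 444 bp and covered 0.221% of the genome. All but 60 were exactly 444 bp wide, as were all but 62 of the 30000 pooled regions, so these values do not measure the extent of binding. Of the 534 entries, 2 repeat the coordinates of another. Their signal, the authors' own value per peak, ran from 74.7 to 1860 with a median of 95.1, and 153 peaks stood at the highest −log10 q in the list, 2.48. Sequencing depth is unknown, since the lists hold no read counts.

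The strongest peak lay on chromosome I at 9382716-9383377 in an intron of ppfr-1, a regulatory subunit of protein phosphatase 4, with a signal of 1860. The non-coding RNA genes F16A11.7 and anr-20 lay within 500 bp. The region X:4606303-4606857, upstream of the RING domain gene spat-3 and beside T13H2.7 and T13H2.9, held 2 summits with signals of 996 and 397. The next were in an intron 513 bp upstream of the TSS of mvk-1 (mevalonate kinase; III:6133331-6133772, 460) and 18 bp upstream of the stomatin family gene sto-4, beside Y71H9A.9 (X:11643856-11644261, 427). Rank 6 was upstream of tasp-1 (III:10759111-10759413, 335) and rank 7 upstream of the ribosomal protein gene rpl-3 (III:3867432-3867719, 333). Both were intergenic.

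Of the other 18 of the 25 strongest peaks, signals ran from 222 to 308, and all were intergenic except the intronic peak nearest cest-16. They lay nearest rpl-15, Y17G9B.5 (a peak that was also in the promoter window of rpl-20), hsp-1 (beside the RNA gene F26D10.23), F44E5.4, which encodes an HSP70 family protein, and cdc-48.1, which encodes an AAA ATPase. Peaks also lay nearest cox-5A (a cytochrome c oxidase subunit), cbp-1 (a histone acetyltransferase; beside R10E11.12), ftt-2 (a 14-3-3 protein; beside F52D10.11, F52D10.12, F52D10.7 and F52D10.9), tag-340 (beside F26F4.14) and R107.5. Peaks nearest egg-5, ins-13 and ZK1248.17 lay at SL2 spliced leader RNA genes, namely sls-2.4 with R12E2.18, sls-2.2 and sls-2.3 with C17C3.22 and C17C3.23, and sls-2.1. The peaks nearest cmd-1 (calmodulin; beside linc-128), W02H3.3, sipa-1, cest-16 and gtr-1 were 1533 to 4783 bp from the nearest TSS.

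All 5 of the strongest summits lay within 200 bp of a perfect GT/CA dinucleotide run, of 188 bp (I:9382981-9383168), 152 bp (X:4606509-4606660, both summits), 160 bp (III:6133462-6133621) and 172 bp (X:11643954-11644125). Such a run of at least 20 bp was found at 6 of the 25 strongest peaks and at 35 of all 534 (6.55%). Of the 38 GT/CA runs of at least 40 bp in the genome, 16 had a thresholded summit (42.1%, 95% interval 26.3 to 59.2%), against 2 of 103 AG/CT runs and 0 of 94 AT runs of that length. The difference from the pooled AG/CT and AT runs had an odds ratio of 70.9 (Fisher's exact test, p = 1.1e-12). Only 7.45% of those AT runs had any candidate region, and against AG/CT runs alone the odds ratio was 36.7 (Fisher's exact test, p = 4.9e-09). The 16 runs include the 4 at the 5 strongest summits, and the test was not repeated without them. Dinucleotide runs were examined after the peak positions were seen.

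**Figure D1:**
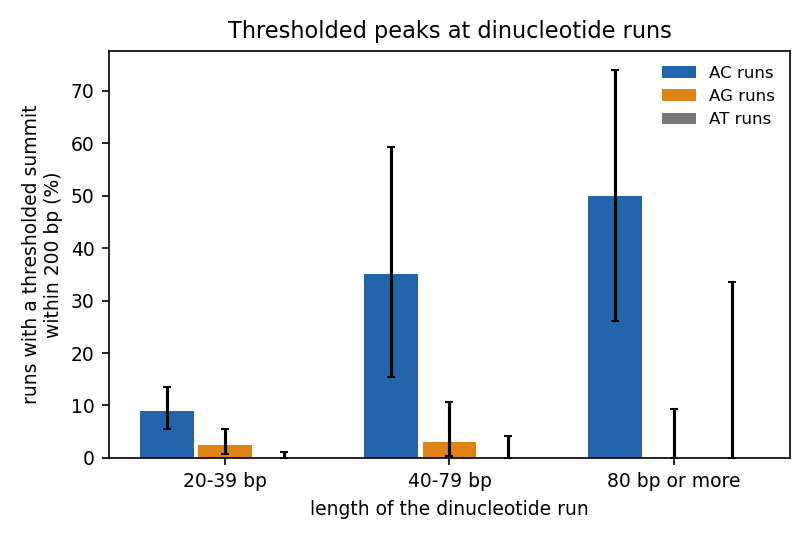
Share of perfect dinucleotide runs in the genome (y axis, %) with a thresholded summit within 200 bp, by run length in bp and repeat unit; bars are shares and lines exact binomial 95% intervals. The share at AC (GT/CA) runs was 8.97% at 20 to 39 bp, 35% at 40 to 79 bp and 9 of 18 runs at 80 bp or more, and AT runs had none.

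Nearly all peaks were listed in both replicates, and fewer ranked high in both. Of the 534 peaks, 527 (98.7%, 95% interval 97.3 to 99.5%) lay in a candidate region of both replicates, against a mean of 3.92% and a maximum of 6.74% in random placements. The thresholded set was itself derived from these lists, so a high share was largely built in and chance placement is a low bar. Among the 534 strongest regions of each list the share in both fell to 259 peaks (48.5%, 44.2 to 52.8%). Of the 534 peaks, 449 were among the strongest regions of replicate 4, 314 among those of replicate 5 and 30 among neither. That share was 79.8% in the 267 peaks of highest pooled signal and 17.2% in the rest, a split that carries no independent evidence, since the pooled signal comes from the same replicates. Across the 527 peaks, which are not independent replicates and were selected on pooled signal from the same data, Spearman's rho was 0.400 (0.289 with reciprocal overlap of 50%, 0.430 with summits within 100 bp) and Pearson's r of log10 signal was 0.612 (0.556 without the 2 farthest peaks), each with a permutation p of 0.0001, the smallest that 10000 permutations can give. The separate IDR fit paired 12206 regions between the lists, with a Spearman's rho of 0.261 over all pairs, and passed 591 at 0.05 and 326 at 0.01. Of the thresholded peaks, 421 (78.8%) had their summit in a region that passed at 0.05.

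**Figure D2:**
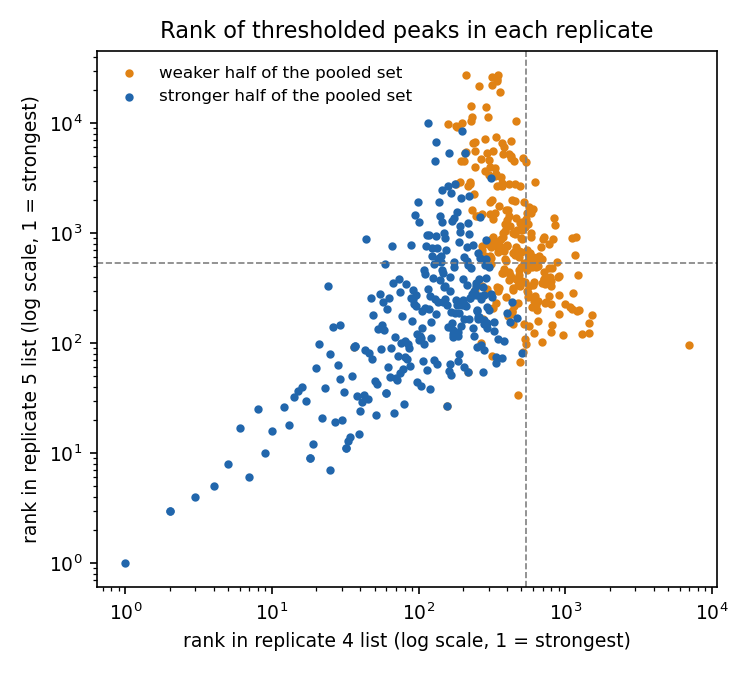
Rank of each of 527 thresholded peaks in the list of replicate 4 (x axis) and of replicate 5 (y axis), both on log scales with 1 the strongest; dashed lines mark rank 534, and blue points are among the 267 strongest of the pooled set. All blue points lie left of the vertical line, while 213 of these 267 peaks were among the 534 strongest regions of replicate 5, as were 314 of all 534 peaks. The colour split carries no independent evidence, since the pooled signal comes from the same replicates.

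Thresholded peaks were mostly outside protein-coding genes and often at promoters. Summits were intergenic, here meaning outside protein-coding genes, in 60.7% of peaks (95% interval 56.4 to 64.8%), against 30.2% of the other 29466 candidate regions (odds ratio 3.57, Fisher's exact test, adjusted p = 2.8e-46). They fell in coding exons in 9.36%, against 35.4% (odds ratio 0.188, Fisher's exact test, adjusted p = 6.2e-43). The intron share, 25.3% against 28.5%, did not pass Fisher's exact test (adjusted p = 0.15). In the promoter window lay 250 summits (46.8%, 42.5 to 51.1%), against 28.2% of other candidates (odds ratio 2.24, Fisher's exact test, p = 2.9e-19) and 25.6% ± 1.88 (SD) of 1000 random placements (permutation p = 0.002, the smallest possible). The promoter share was 47.9% in the 267 strongest peaks and 45.7% in the rest, a difference that did not pass the test (Fisher's exact test, adjusted p = 0.997).

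Of the 534 summits, 121 (22.7%) lay within 500 bp of a tRNA, snoRNA, snRNA or miRNA gene. No untagged control was analysed here. Whether these peaks, or those at the other non-coding RNA genes below, are binding of ZTF-3 was therefore not tested. A tRNA gene lay within 500 bp of 59 summits (11.05%, 95% interval 8.52 to 14.02%, against 1.52% of other candidates; odds ratio 8.03, Fisher's exact test, adjusted p = 6.2e-30). snoRNA genes, which guide RNA modification, lay by 42 summits (7.87% against 0.821%, odds ratio 10.3, adjusted p = 9.6e-26). snRNA genes, the SL2 spliced leader genes among them, lay by 16 (3.00% against 0.255%, odds ratio 12.1, adjusted p = 1.1e-11). Other non-coding RNA genes lay by 160 (29.96% against 10.1%, odds ratio 3.82, Fisher's exact test, adjusted p = 2.3e-35). miRNA genes lay by 6 (odds ratio 2.76, adjusted p = 0.037), and piRNA genes by 12 (odds ratio 0.949, adjusted p = 1). rRNA genes lay by 0 of 534 summits and by 1 of the other 29466 candidates, so the 0 says nothing about binding there. The tRNA odds ratio fell to 4.66 without replicate 4, and in intergenic summits alone, chosen after seeing the data, the odds ratios were 4.96 for tRNA, 6.70 for snoRNA, 6.65 for snRNA and 2.37 for other non-coding RNA genes, all past the threshold. The miRNA call was lost without replicate 4 (exact test, adjusted p = 0.187), at a distance of 200 bp (0.46), in intergenic summits alone (0.425) and in the 267 strongest peaks (1), and the range over alternatives was 0.00343 to 1.

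**Figure D3:**
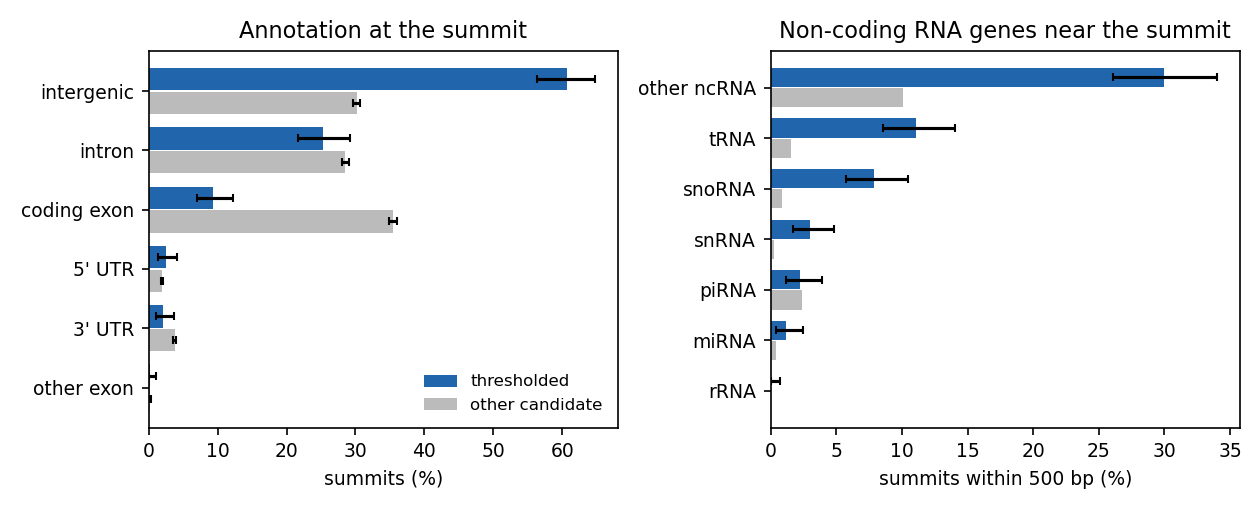
Left, annotation at the summit; right, share of summits within 500 bp of a gene of each non-coding RNA class, both in % (x axes) for the 534 thresholded peaks (blue) and the other 29466 candidate regions (grey). Lines are exact binomial 95% intervals, drawn on the right for thresholded peaks only. Intergenic summits, meaning those outside protein-coding genes, made up 60.7% of thresholded peaks and 30.2% of the others.

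Chromosomes III and X held more peaks than their share of candidate regions, and IV and V fewer. Chromosome III had 110 peaks (20.6%, 1.35 times its share, exact binomial test, adjusted p = 0.0054) and X had 23.03% of all peaks (1.22 times, adjusted p = 0.0263). Chromosome V had 78 (0.737 times, exact binomial test, adjusted p = 0.00694) and IV had 59 (0.734 times, adjusted p = 0.0183). Chromosomes I (88 peaks) and II (76) did not pass. Of the 59 peaks near tRNA genes, 36 were on X, and without these 59 peaks X held 87 of 475, which is 0.990 times its share (exact binomial test, adjusted p = 0.953; range over alternatives 0.00264 to 0.953). Without replicate 5, X stood at 1.17 times its share and missed the threshold (exact binomial test, adjusted p = 0.111). Chromosome IV missed it in the 267 strongest peaks at 0.771 times its share (exact binomial test, adjusted p = 0.185), without replicate 4 at 0.808 times (0.0955) and without replicate 5 at 0.863 times (0.278; range over alternatives 0.000146 to 0.278).

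Of the 35 lists, 4 had promoter peaks more often than other genes: ribosomal proteins, heat shock proteins, translation factors and the respiratory chain. No untagged control was analysed here, so whether these promoter peaks are binding of ZTF-3 was not tested. In all, 309 protein-coding genes had a thresholded summit in the promoter window, 4.35% of the 7110 with any candidate summit there. Ribosomal protein genes had one at 13 of 43 members (30.2%, odds ratio 9.91, Fisher's exact test, adjusted p = 6.1e-07), with signals of 333 at rpl-3, 272 at rpl-20, 231 at rpl-15 and 204 at rpl-35. Heat shock protein genes had one at 5 of 14 (odds ratio 12.4, Fisher's exact test, adjusted p = 0.0038): hsp-1 (228), hsp-90 (154), hsp-3 (151), hsp-60 (144) and hsp-110, which was named after its value was seen (93.9). Translation factor genes had one at 5 of 22 (odds ratio 6.56, Fisher's exact test, adjusted p = 0.0188), the strongest at iff-2 (207), eef-2 (107), eef-1G (85.3) and eef-1A.2 (83.2). Respiratory chain genes had one at 5 of 21 (odds ratio 6.97, Fisher's exact test, adjusted p = 0.0188), the strongest at cox-5A (224), cox-5B (134), atp-1 (105) and cox-6A (77.8). The cox-6A peak also lay within 500 bp of the snRNA gene F54D8.7. The ribosomal odds ratio was 6.40 without replicate 4, 6.22 without replicate 5 and 4.34 by nearest TSS. That of heat shock genes was 6.90 by nearest TSS and 19.01 against all protein-coding genes, both past the threshold. Without replicate 4 the heat shock call was lost at an odds ratio of 9.17 (exact test, adjusted p = 0.0935; range over alternatives 0.000212 to 0.0935), and the translation and respiratory chain calls at 3.33 (0.652; range 0.00254 to 0.652) and 3.25 (0.733; range 0.00254 to 0.733). Translation and respiratory chain genes also missed the threshold without replicate 5, at odds ratios of 5.34 each (exact test, adjusted p = 0.0762 each), with the window of 500 bp upstream, at 6.48 and 6.05 (0.067 each), and without peaks near small RNA genes, at 5.72 and 6.06 (0.0748 each). In the 267 strongest peaks they missed it at 4.44 and 7.46 (exact test, adjusted p = 0.495 and 0.125), and respiratory chain genes by nearest TSS at 4.31 (0.102).

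**Figure D4:**
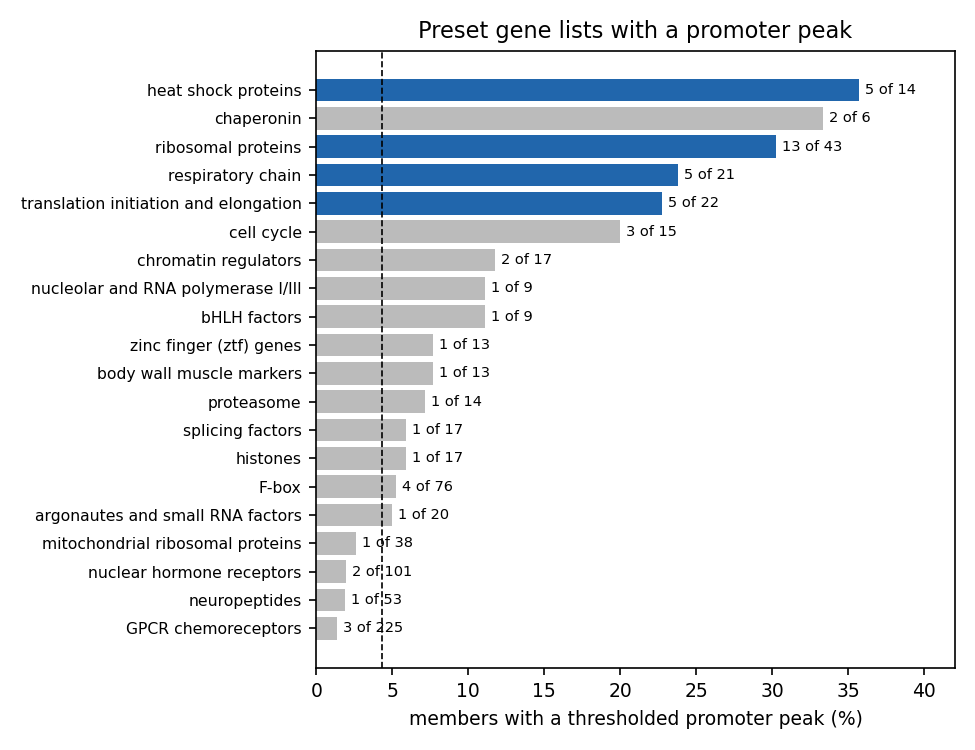
Share of each preset list's members with a thresholded promoter peak (x axis, % of members with any candidate summit in the promoter window), for the 20 lists with at least 1 such member; blue bars passed Fisher's exact test after adjustment over 35 lists, and the dashed line is the median share of genes outside each list. Ribosomal proteins stood at 30.2% and GPCR chemoreceptors at 1.33%.

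The other 31 lists did not pass. Chaperonin genes had a promoter peak at 2 of 6 (cct-8 and cct-1; exact test, adjusted p = 0.126), cell cycle genes at 3 of 15 (pcn-1, efl-1 and lin-35; 0.126) and chemoreceptor genes of the GPCR class at 3 of 225 (sre-23, sri-5 and srh-2; odds ratio 0.291, 0.126). Chaperonins passed against all protein-coding genes (odds ratio 21.3, Fisher's exact test, adjusted p = 0.0366; range over alternatives 0.0366 to 1), and by nearest TSS had no member with a peak. The chemoreceptor share passed as lower against all protein-coding genes (Fisher's exact test, adjusted p = 1.9e-05) and by nearest TSS (0.00545), over a range of 1.9e-05 to 0.454, and its odds ratio was 0.181 without replicate 4 and 0.265 without replicate 5, neither past the threshold. Chromatin regulators had 2 of 17 (cbp-1 and lin-53; odds ratio 2.95, and 1.05 without replicate 4), nuclear hormone receptors 1.98% of members (nhr-68 and nhr-35; odds ratio 0.441, and 0.245 without replicate 4) and F-box genes 4 of 76 (fbxb-58, fbxa-202, fbxb-85 and fbxa-90). The peak at fbxa-90 is the same as that at efl-1, so it counts in both lists. A single member was found for mitochondrial ribosomal proteins (mrpl-23), histones (his-37), bHLH factors (hlh-11), ztf zinc finger genes (ztf-7), the proteasome (rpn-3, at the peak shared with hsp-110), neuropeptides (ins-39), splicing factors (snr-4), nucleolar and RNA polymerase I and III genes (pro-1), argonaute and small RNA factors (ego-1) and body wall muscle markers (act-4). The peaks at mrpl-23 and sre-23 also lay within 500 bp of the snoRNA genes T08B2.13 and ZK265.10. That at snr-4 lay within 500 bp of the snRNA gene T11F9.15. Without peaks near small RNA genes the odds ratios of mitochondrial ribosomal proteins and splicing factors were 0. The summit at act-4 lay on a 36 bp GT/CA run inside the gene. The 15 lists with no member were markers of pan-neuronal, intestine, germline and oocyte, hypodermis and cuticle, and pharynx identity, and collagens, major sperm proteins, vitellogenins, homeobox factors, vacuolar ATPase, C-type lectins, cytochrome P450 and UGT enzymes, tRNA synthetases, RNA polymerase II with Mediator, and signalling genes. They had only 3 to 68 members with a candidate summit, which limits what a count of 0 can show.

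Of 2080 canonical 6-mers, 109 were more frequent at the 534 summits than at 2670 matched control windows. AGAGAC was in 18.7% of peak windows and 5.92% of controls (odds ratio 3.67, one-sided Fisher's exact test, adjusted p = 8.0e-16). ACGCAG was in 14.04% against 4.27% (3.67, 5.0e-12) and GAGAGA in 21.9% against 9.33% (2.73, 6.2e-12). ACACAC was in 17.6% against 6.67% (3.00, 1.8e-11) and GACGCA in 12.4% against 3.90% (3.49, 3.6e-10). In the test of 8-mers the lowest p was that of AGACGCAG, in 7.68% of peak windows against 1.46% (odds ratio 5.60, one-sided Fisher's exact test, adjusted p = 9.8e-09). It contains both GACGCA and ACGCAG, and it overlaps AGAGACGC, an 8-mer past the threshold that contains AGAGAC. The named 6-mers and the count of 109 are therefore not separate signals. The odds ratios of AGAGAC and GACGCA fell to 2.10 and 1.94 without replicate 4, and that of GACGCA to 2.31 without replicate 5. Against flanks of the same summits those of ACGCAG and GACGCA were 6.22 and 5.58, that of ACACAC was 4.90 in the 267 strongest peaks, and all of these were past the threshold. Without peaks at GT/CA runs, left out after the data were seen, ACACAC was in 13.8% of peak windows against 6.25% (odds ratio 2.41, one-sided Fisher's exact test, adjusted p = 5.6e-06; range over alternatives 6.0e-13 to 7.6e-05), and the odds ratio of ACGCAG was 3.94.

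The transgene carries ztf-3 and unc-119. No thresholded peak lay within 5000 bp of ztf-3 (I:286040-289185, minus strand) or within 20000 bp of unc-119 (III:10902641-10908935, plus strand). Within 20000 bp of ztf-3 lay 3 thresholded summits (I:296127, I:297513 and I:299856), all in introns and nearest the TSS of C53D5.1, where the chromosome's average gives 0.252. The replicates differed there, with 10 candidate regions in replicate 4 and 26 in replicate 5, against averages of 12.7 and 13.5, and within 5000 bp 1 and 11, against 3.86 and 4.10.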

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

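The intergenic comparison of RNA genes, the chromosome shares without peaks at tRNA genes and the 6-mers without peaks at GT/CA runs were chosen after the data were seen. The promoter excess and the rank correlation kept their direction and their side of the threshold under every alternative run for them. Of 124 alternatives for single lists, classes, chromosomes and 6-mers, 98 kept both, 19 kept the direction but no longer passed, 3 passed where the main test did not and 4 reversed. These cover only the 5 named 6-mers, the 5 RNA classes and 4 chromosomes that passed, and the 7 lists with an unadjusted p under 0.05. For the other 28 lists the odds ratio crossed 1 in 28 of 196 alternatives, in 16 lists, such as mitochondrial ribosomal proteins (0.594 to 1.35) and F-box genes (1.23 to 0.286) without replicate 4. For piRNA genes it crossed 1 at 200 bp (0.949 to 1.03). None of these passed. A reversal here means a value on the other side of 1, whatever its size, and none passed the threshold in that direction. The reversals were miRNA genes in the 267 strongest peaks (odds ratio 0.912, from 1 summit), chromosome X without peaks near tRNA genes (0.990 times its share), chaperonins by nearest TSS (0) and cell cycle genes without replicate 4 (0, and 5.66 without replicate 5). They show the loss of an excess, not an opposite effect. Support in both candidate lists was 91.2% with reciprocal overlap of 50%, 86.9% with summits within 100 bp and 100% in the 267 strongest peaks. Support in both lists' 534 strongest regions was 41.4%, 41.4% and 79.8% in that order. The first 2 of these settings ask for a closer match by construction. The own IDR fit passed 326 regions at 0.01, fewer than the 591 at 0.05 and the 534 of the deposited set. Past the threshold were 2 to 3 chromosomes, 1 to 2 gene lists and 70 to 102 6-mers when a replicate was left out, against 4, 4 and 109. Gene lists past it numbered 6 against all protein-coding genes, 4 by nearest TSS, with chemoreceptors in and the respiratory chain out, and 2 each in the 267 strongest peaks, with the 500 bp window and without peaks near small RNA genes. The cause of these shifts in counts was not tested. Against flanks of the same summits 321 6-mers passed, and 67 of 32896 8-mers did, a test with more k-mers; the cause was not tested. Depth is unknown, so how far replicate 5's weaker support reflects fewer reads cannot be said.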

Other observations

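SL2 RNA genes, peak classes by sequence, dinucleotide runs by length, the X share and the ztf-3 windows were examined after the related results were seen; the test comparing GT/CA with AG/CT and AT runs was set before its result was seen.

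Peaks at small RNA genes lay less often in protein-coding promoter windows than the other peaks. A tRNA, snoRNA, snRNA or miRNA gene lay within 500 bp of 121 of the 534 summits (22.7%), and only 34 of these 121 (28.1%) also lay in a protein-coding promoter window, against 216 of the other 413 (52.3%; Fisher's exact test, odds ratio 0.356, p = 2.6e-06). Both groupings are by position and no baseline of small RNA genes without a peak was used. The difference can therefore reflect only where such genes lie. A further 197 summits (36.9%) had neither. None of the 5 named 6-mers differed past the threshold between windows at small RNA genes and the others (Fisher's exact test, adjusted p 0.0703 to 0.417). The odds ratios were 0.433 for GACGCA, 0.498 for AGAGAC, 0.545 for ACGCAG, 0.599 for GAGAGA and 0.775 for ACACAC. Among SL2 RNA genes, whose short leader is spliced onto downstream genes of operons, 7 of 18 had a thresholded peak within 500 bp, at 6 distinct peaks: sls-2.1, sls-2.2, sls-2.3, sls-2.4, sls-2.8, sls-2.9 and sls-2.14, of which the first 4 named lay at peaks among the 25 strongest. Of the SL2 genes, 17 had a candidate region. Of the 12 annotated SL1 RNA genes (sls-1), 0 had one; reads from near-identical copies can be lost in alignment, so this does not show a lack of binding.

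The strongest peaks lay on long GT/CA runs. If any long dinucleotide run collected reads, AG/CT and AT runs of at least 40 bp would carry peaks as often, and they did not: 2 of 197 against 16 of 38 (Fisher's exact test, p = 1.1e-12), or 2 of 103 against AG/CT runs alone (p = 4.9e-09). The 16 include the 4 runs at the 5 strongest summits, and the test was not repeated without them. Any candidate region lay at 84.2% of these GT/CA runs, 42.7% of the AG/CT runs and 7.45% of the AT runs. The test therefore cannot tell whether reads are recovered unequally by repeat unit. Signal rose with run length over the 142 GT/CA runs with a candidate summit (Spearman's rho 0.289, one-sided permutation p = 0.0004, and rho 0.274 without the 2 longest). The runs at the 5 strongest summits prompted this test of run length, and over the 138 others rho was lower, 0.227 (one-sided permutation p = 0.0036). A rise is what direct binding of ZTF-3 to the repeat would give, and so would reads of other GT/CA runs placed there or a strain with longer runs. These readings stay open as hypotheses, because no untagged control was analysed here, and no biological explanation was tested.

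The excess of peaks on X may rest on tRNA genes. Without the 59 peaks near them X held 0.990 times its share, while chromosome III stayed at 1.49 times (exact binomial test, adjusted p = 0.00011). Of the annotated tRNA genes 276 of 612 (45.1%) are on X, and 41 of these 276 (14.9%) had a peak within 500 bp, against 26 of 336 on autosomes (7.74%; Fisher's exact test, odds ratio 2.08, p = 0.00609). Neighbouring tRNA genes can share a peak, so this p is too small. Whether these peaks are binding of ZTF-3 or reads that highly transcribed genes collect in any ChIP was not tested, and no biological explanation was tested.

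Extra transgene copies were weighed for the thresholded summits beside ztf-3. They would raise reads around the gene in both replicates of the same strain. Among 3006 windows of that size on chromosome I, replicate 5 stood at the 98.6 percentile (26 regions) but replicate 4 at the 36.6 percentile, with 10 regions (95% Poisson interval 4.80 to 18.4) where the 95th percentile is 22. Within 5000 bp replicate 4 had 1 region where the chromosome's average gives 3.86, and replicate 5 had 11 where it gives 4.10. By these counts the replicates point different ways. By strength both had a high-ranked region within 20000 bp, rank 266 of 30000 in replicate 4 (summit I:299981) and rank 95 of 30000 in replicate 5 (I:296119). Within 5000 bp the best ranks were 7459 and 801. The thresholded list, with 3 summits, stood at the 99.7 percentile of the same 3006 windows. The strain of the control is not given in the sources used here. Extra copies therefore stay open, as does a difference between the replicates' libraries.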
